A study of Caenorhabditis elegans with 2 samples.

How the data were processed

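SNPC-4 was mapped by transcription factor ChIP-seq in whole young adult worms of strain OP179, with chromatin fragmented by sonication and 2 biological replicates. Per the labels, the worms stably expressed SNPC-4 with a C-terminal GFP-FLAG tag. The labels name a possible control experiment, which is not analysed here. No other group, tissue or condition was present, so no test between groups of samples was made.

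The deposited files were narrowPeak lists on ce10 and on ce11. For each build they comprised a list thresholded by the irreproducible discovery rate (IDR), described by the authors as the optimal one, the pooled list given to IDR, and the list of each replicate given to IDR. The lists given to IDR are labelled as peaks and background, so not every entry in them is a called peak. They come from the ChIP samples and are not lists of control DNA. The signal of each peak in the deposited lists is the enrichment value of the authors' peak caller, whose scale relative to the control is not stated. It served here to describe, rank and filter peaks within a list. The deposited -log10 q values were all 3.59 in the thresholded ce11 list and carried no ranking there. The deposited lists also gave the summit position in bases from the start of the peak. The peak caller, its version, the read aligner and the IDR threshold are not given in the sources used here. Of the thresholded ce11 peaks 60.0% had the width of 380 bp, and 2304 different intervals held the 2345 summits. Read counts were not used here, so no depth per sample could be given, and all intervals and limits cover counting error of peaks or genes only.

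Gene positions came from the Ensembl release 115 annotation of WBcel235, which is ce11, and gene symbols and tRNA products came from the RefSeq annotation, matched by WormBase gene identifier. Symbols were first read from the Ensembl annotation, which gave some genes shared or wrong symbols. The change was made after first results had been seen, with the lists' symbols left as fixed, and added members to the spliced leader class and to the lists of heat shock proteins and neuropeptides. Peak ends were checked against the chromosome lengths of the reference. No coordinates were converted between builds, and a ce10 annotation was not used here, so that gene comparisons used ce11. Genes were grouped into 9 classes by annotated biotype, with spliced leader genes taken by their symbols *sls-1* and *sls-2*. Genes whose 5′ ends coincide counted as 1 locus where shares of genes were given.

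The main choices were fixed before the data were examined. A peak was near a gene when its summit lay within 200 bp of the 5′ end. The expected number per class came from 10000 placements of the summits at random within their chromosome, two-sided, with Benjamini-Hochberg adjustment over the classes. Chromosome counts were compared with 10000 placements by length over the 6 nuclear chromosomes. Shares of genes were compared with protein-coding genes by two-sided Fisher's exact tests with adjustment, and shares have Wilson 95% intervals. A count of 0 is given with the share that 3 counts would make. The threshold was an adjusted p of 0.05. In the text a permutation p comes from placements, shifts or resamples and an exact p from Fisher's test. Values per replicate came from the 2345 strongest peaks of each replicate list, and are given as mean and SD with n = 2, or as the pair of values. Clusters of piRNA genes were runs of 100 kb windows of chromosome IV with at least 20 annotated piRNA genes, joined over gaps of up to 500 kb, tested by 10000 circular shifts. The piRNA motif was searched with up to 1 mismatch at 30 to 70 bp upstream of piRNA genes. Within 100 bp of summits the exact motif was searched on either strand, so the shares at genes and at summits follow unlike rules. Words of 8 bases within 50 bp of summits were compared on both strands together by Fisher's exact test with adjustment. Median signals were compared by permutation with 100000 resamples (10000 for ranks), each peak counting for a single group there. Chance sharing between replicates came from 1000 placements.

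Genes were named by a fixed rule: the 20 peaks with the highest signal with the gene of the nearest 5′ end, the up to 3 genes with the strongest peak in each RNA class, 12 genes chosen in advance whatever their value, and the 3 strongest members of each passing list. Lists by symbol were ribosomal proteins, histones, collagens, neuropeptides, chemoreceptors, major sperm proteins, vitellogenins, heat shock proteins, piRNA factors, and germ granule and small RNA factors. Sequence uniqueness of a gene was the share of 32-base words within 200 bp of the 5′ end that occur in the genome at a single place, and a named gene with under 80% of such words is called uncertain. Families of snRNA were assigned from conserved elements of U1, U2, U4, U5 and U6 at set positions, written down before the gene sequences were read, and the SmY family by symbol. The placement test was tested on simulated data of 2345 peaks. With 50 peaks planted near tRNA or snRNA genes it called the class in 40 of 40 simulations, and near protein-coding genes in 36 of 40. With 0 planted it called tRNA and snRNA genes in 0 of 40 simulations and protein-coding genes in 3 of 40.

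Alternatives covered the stronger part of the list by signal (1172 peaks), each replicate alone, distances of 100 bp and 500 bp, 5′ ends inside the peak, other overlap rules, other backgrounds, unique flanks, stricter clusters, the exact motif, merged peaks and the ce10 list. Those added after the data were seen were the list without mitochondrial peaks, protein-coding results without peaks near noncoding RNA genes, the count of peaks in the ce10 list, the summit motif with placement inside the same part of the chromosome, the other chromosomes with IV left out, and the gene lists within 500 bp without peaks near noncoding RNA genes. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.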

Results

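Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map SNPC-4 in whole young adult *Caenorhabditis elegans* of mixed sex. SNPC-4 is a subunit of SNAPc, the transcription factor complex of small nuclear RNA (snRNA) and spliced leader RNA genes, and is also known as a factor for the piRNA genes of chromosome IV. The worms, strain OP179, carried SNPC-4 with a GFP-FLAG tag at its C-terminus from an integrated transgene, in a background mutated in *unc-119*. The only group was formed by 2 biological replicates. The files held lists of peaks and no read counts, so the sequencing depth was unknown. The thresholded list on ce11 held 2345 peaks, 2318 of them on the nuclear chromosomes. Their signal, the value that the authors' peak caller gave each peak, ran from 41.5 to 3238 with a median of 60.9. The list of replicate 1 given to IDR, which by its label holds peaks and background, had 27573 entries. That of replicate 2 had 30000, as did the pooled list.

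The question of which gene groups SNPC-4 occupied was addressed by counting peaks whose summit lay within 200 bp of an annotated 5′ end, and the strongest nuclear peaks sat at structured noncoding RNA genes. Spliced leader RNA genes, whose products are trans-spliced onto messenger RNAs, had 20 peaks against 0.283 expected from random placement within each chromosome, a ratio of 70.7. The genes of snRNAs, the RNA components of the spliceosome, had 67 peaks against 1.10, a ratio of 60.8. Small nucleolar RNA (snoRNA) genes, whose products guide RNA modification, had 97 peaks against 3.25, a ratio of 29.9. Transfer RNA (tRNA) genes had 269 peaks against 13.7, a ratio of 19.6. Without the mitochondrial peaks, an alternative chosen after the data were seen, the tRNA count was 262 against 4.90, a ratio of 53.4. Each of these ratios had an adjusted permutation p of 0.000225 over the 9 classes, from an unadjusted p of 0.0002, the smallest that 10000 two-sided placements can give.

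Both replicates held these 4 groups. Peaks near snRNA genes made up 2.84% ± 0.0302 (SD, n = 2) of the 2345 strongest peaks of each replicate, and peaks near spliced leader genes 0.874% ± 0.0302 (SD, n = 2). The snoRNA share was 4.05% in both replicates, and the tRNA share, mitochondrial genes included, was 11.5% ± 1.96 (SD, n = 2). Of the 20 strongest nuclear peaks, 19 lay near a gene of these groups, as did 72 of the 100 strongest (72.0%, Wilson 95% interval 62.5 to 79.9). Among the 500 strongest nuclear peaks the share was 45.4% (41.1 to 49.8), and among the remaining 1818 it was 11.9%.

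The strongest nuclear peak, on ce11 chromosome II, lay upstream of the snoRNA gene *Y53F4B.47* (15025814 to 15025893), outside protein-coding genes. Its signal was 2805, with 1411 in replicate 1 and 1414 in replicate 2, and its summit lay 75 bp upstream of the 5′ end. A peak with signal 2554 (replicates 1138 and 1381) lay in an intron of *pcyt-2.1* on chromosome I, with its summit 47 bp upstream of the 5′ end of the snoRNA gene *Y37E3.20* (2085037 to 2085155) and 37 bp downstream of that of the noncoding RNA gene *Y37E3.29* (2084806 to 2085027). The snoRNA gene *W04D2.7* (V, 12491280 to 12491346), in an intron of *inx-11*, had signal 2078, with 1009.7 and 1096 in the replicates. *C16D9.11* (V, 8228900 to 8228969), a snoRNA gene in an intron of *rol-3*, had signal 2038, with 1030.1 and 1008 in the replicates. The snoRNA genes *F59C6.15*, *Y55F3BR.9*, *C08D8.3*, *Y74C9A.6*, *F01D5.12*, *T26A8.6* and *ZK994.7* also stood next to peaks among the 20 strongest, with signals between 1445 and 1869 and summits 39 to 86 bp upstream. Of these, *F59C6.15* is uncertain, as 67.8% of the words in its flanks occurred at a single place. The noncoding RNA genes *T06D8.17* (II, in an intron of *plpr-1*) and *ZK265.11* (I, by a summit in the 3′ UTR of *ceh-8*) had signals of 1599 and 1387.

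Among spliced leader genes, *sls-2.1* (II, 5844865 to 5844974, outside protein-coding genes) had the highest signal, 2151, with 1019 in replicate 1 and 1113 in replicate 2. The genes *sls-2.8* (III, 12250465 to 12250575) and *sls-2.16* (III, 7141391 to 7141499, in an intron of *glr-2*) followed with signals of 1679 and 1607, and *sls-2.4* (I, 4172206 to 4172315) with 1479. The snRNA gene with the highest signal was *W05B2.8* (III, 10989679 to 10989780, in an intron of *dhc-4*), at 1493, with 837 and 638 in the replicates. It was followed by *C52E4.8* (V, 11980118 to 11980261) with signal 1159 and by *sup-6* (II, 12944803 to 12944967), a U1 snRNA gene known from suppressor mutations, with signal 981. Of the 32-base words in the flanks of *W05B2.8* and *C52E4.8*, 79.5% and 67.8% occurred at a single place in the genome, so the assignment of their peaks is uncertain. The isoleucine tRNA gene *C27A2.t1* (II, 5057447 to 5057520) had signal 1248, with 604 and 644 in the replicates, and the phenylalanine tRNA gene *ZC412.t1* (V, 14876389 to 14876461) had signal 1035, with 587 and 465.

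Seen from the genes, peaks were common at spliced leader, snRNA and tRNA genes, less so at snoRNA genes, and rare at protein-coding genes. Of 31 spliced leader genes, 18 had a peak (58.1%, Wilson 95% interval 40.8 to 73.6), and of 99 snRNA genes 56 had one (56.6%, 46.7 to 65.9). As annotated, the snRNA class includes *mir-1831*, which lies inside *sup-39*, and *T27E4.22*, which overlaps *T27E4.12*, so that in these pairs the same peak counts for both genes. A peak was present at 294 of 634 tRNA genes (46.4%, 42.5 to 50.3) and at 95 of 346 snoRNA genes (27.5%, 23.02 to 32.4). Only 517 of 19978 protein-coding genes had one (2.59%, 2.38 to 2.82). Against protein-coding genes the odds ratios were 52.1 for spliced leader genes (adjusted p = 7.33e-21), 49.0 for snRNA genes (4.12e-60), 32.5 for tRNA genes (1.06e-253) and 14.2 for snoRNA genes (1.06e-63), by two-sided Fisher's exact tests. The spliced leader share was 58.1% in both replicates, and the tRNA share was 46.0% ± 7.03 (SD, n = 2). Among the 20 spliced leader genes whose flanking sequence as a whole occurs in the genome at a single place, 18 had a peak (90.0%). Such flanks can still hold repeated stretches, as at *sls-1.12*, where 8.65% of 32-base words were unique. Of the 14 spliced leader genes with at least 80% unique words, 13 had a peak. Genes are not independent samples, and the intervals cover counting error only.

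**Figure D1:**
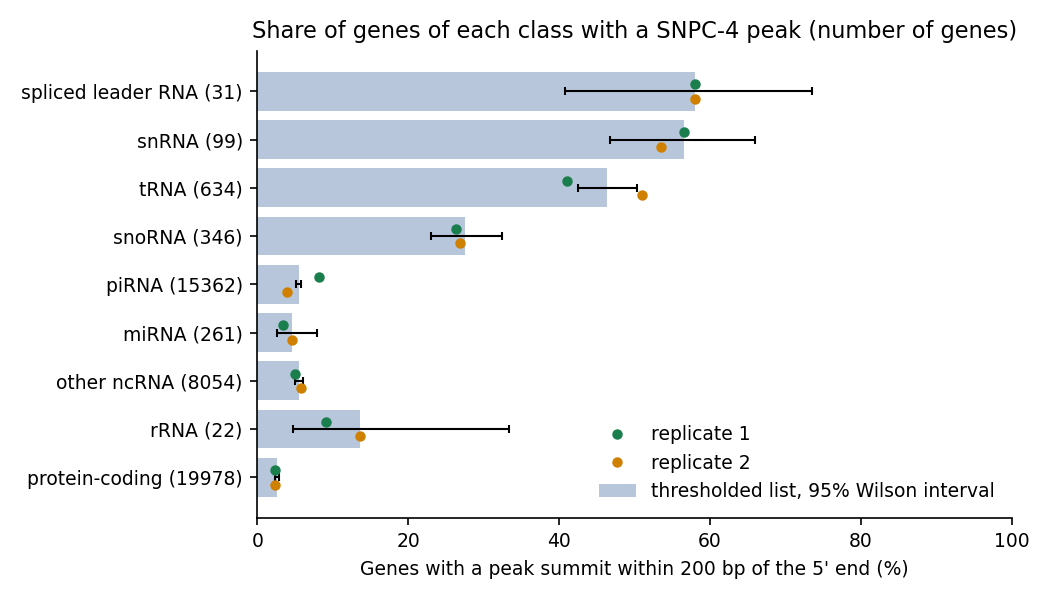
Share of genes of each class, in percent, with a summit of a SNPC-4 peak within 200 bp of the 5′ end, with the number of genes in brackets. Bars show the thresholded list with its 95% Wilson interval and points the 2345 strongest peaks of each replicate; spliced leader RNA genes reached 58.1% and protein-coding genes 2.59%.

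Other noncoding RNA genes and microRNA genes also had more peaks nearby than random placement gave. The class of other noncoding RNA had 381 peaks against 60.8 expected (ratio 6.27, adjusted permutation p = 0.000225), of which 211 were also near a spliced leader, snRNA, tRNA or snoRNA gene. Within this class, *rpr-1* (I, 13463955 to 13464207, in an intron of *ints-8*), the gene of the RNA component of RNase P, had signal 1167, with 617 and 544 in the replicates. *mrpr-1* (II, 7200233 to 7200418), the gene of the RNA of RNase MRP, had signal 436, with 239 and 197 in the replicates. The Y RNA gene *yrn-1* (IV, 7499508 to 7499612) and the noncoding RNA gene *rncs-1* (X, 1011501 to 1012347) had no peak within 200 bp. MicroRNA genes had 12 peaks against 2.34 (ratio 5.13, adjusted permutation p = 0.000225), the strongest at *mir-2214* (III, 7278715 to 7278778) with signal 862, then at *mir-8196.1* (X, 2328994 to 2329124) with 491 and *mir-8196.2* (X, 14324355 to 14324517) with 332. The developmental microRNA genes *let-7* and *lin-4* had none within 200 bp of the annotated 5′ end. Counted by gene, 12 of 261 microRNA genes had a peak (4.60%, 2.65 to 7.86), which did not differ from protein-coding genes past the threshold (adjusted exact p = 0.0501). Ribosomal RNA genes had 3 peaks against 1.68 (adjusted permutation p = 0.473), 2 of them at mitochondrial genes and 1, with signal 199, near *rrn-4.15* (V, 17428879 to 17428996), which is uncertain for its repeated flanks. Their share by gene, 13.6%, was above that of protein-coding genes (adjusted exact p = 0.0213), and without the mitochondrial peaks it was 5.0% (adjusted exact p = 0.405).

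Protein-coding 5′ ends had 463 peaks nearby against 187 expected, a ratio of 2.48 (adjusted permutation p = 0.000225). Without peaks that were also near a structured or other noncoding RNA gene, 413 peaks remained against 138, a ratio of 3.002 (adjusted permutation p = 0.00045). The class held 19.7% of the thresholded peaks (18.2 to 21.4) and 18.0% ± 0.271 (SD, n = 2) of the strongest peaks of each replicate. By location, 62.9% of nuclear summits lay outside protein-coding genes, where random placement put 37.6%. Coding exons held 2.85% of summits against 24.2% by placement, and introns 29.2% against 33.4%. No 5′ end of the 9 classes lay within 200 bp of 999 peaks (42.6%).

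Whether SNPC-4 peaks gathered on chromosome IV, which holds 95.8% of the annotated piRNA genes, was the next question, and they did. Chromosome IV had 856 of the 2318 nuclear peaks (36.9%, 35.0 to 38.9) against 404 expected from its length, a ratio of 2.12 (adjusted permutation p = 0.0003 over 6 chromosomes, from an unadjusted p of 0.0002, the smallest that the placements can give). The share was 41.6% in replicate 1 and 31.2% in replicate 2, or 36.4% ± 7.37 (SD, n = 2). Since the total is fixed, this excess lowers the ratios of the other chromosomes, which were 0.576 for V, 0.722 for X, 0.802 for I, 0.860 for II and 0.955 for III. Compared among themselves with IV left out, a test chosen after the data were seen, V was lower (ratio 0.755, adjusted permutation p = 0.0005) and III and II were higher (ratios 1.25 and 1.13, adjusted permutation p = 0.0005 and 0.044). Chromosomes I (1.05) and X (0.946) were not called in that test (adjusted permutation p = 0.393 and 0.37).

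Along chromosome IV the peaks crowded into the piRNA clusters. The clusters, defined as runs of windows rich in annotated piRNA genes, ran from 4800001 to 7000000, from 9100001 to 9200000 and from 13500001 to 17300000. The cluster at the right end held 11534 piRNA genes and 508 peaks, or 134 peaks per Mb, and the left cluster held 2807 piRNA genes and 111 peaks, or 50.5 per Mb. Outside the clusters chromosome IV had 20.3 peaks per Mb, and the other nuclear chromosomes had 17.7. Together the clusters held 625 of the 856 peaks (73.0%, 69.9 to 75.9) in 34.9% of the chromosome, against 299 expected under circular shifts (ratio 2.09, permutation p = 0.001, two-sided). The share was 77.9% in replicate 1 and 69.8% in replicate 2, or 73.8% ± 5.78 (SD, n = 2). Of the compared entries of chromosome IV in the pooled list below the threshold, which by label include background, 66.02% lay in the clusters. In the right cluster, replicate 1 had 165 and replicate 2 had 103 of its strongest peaks per Mb.

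**Figure D2:**
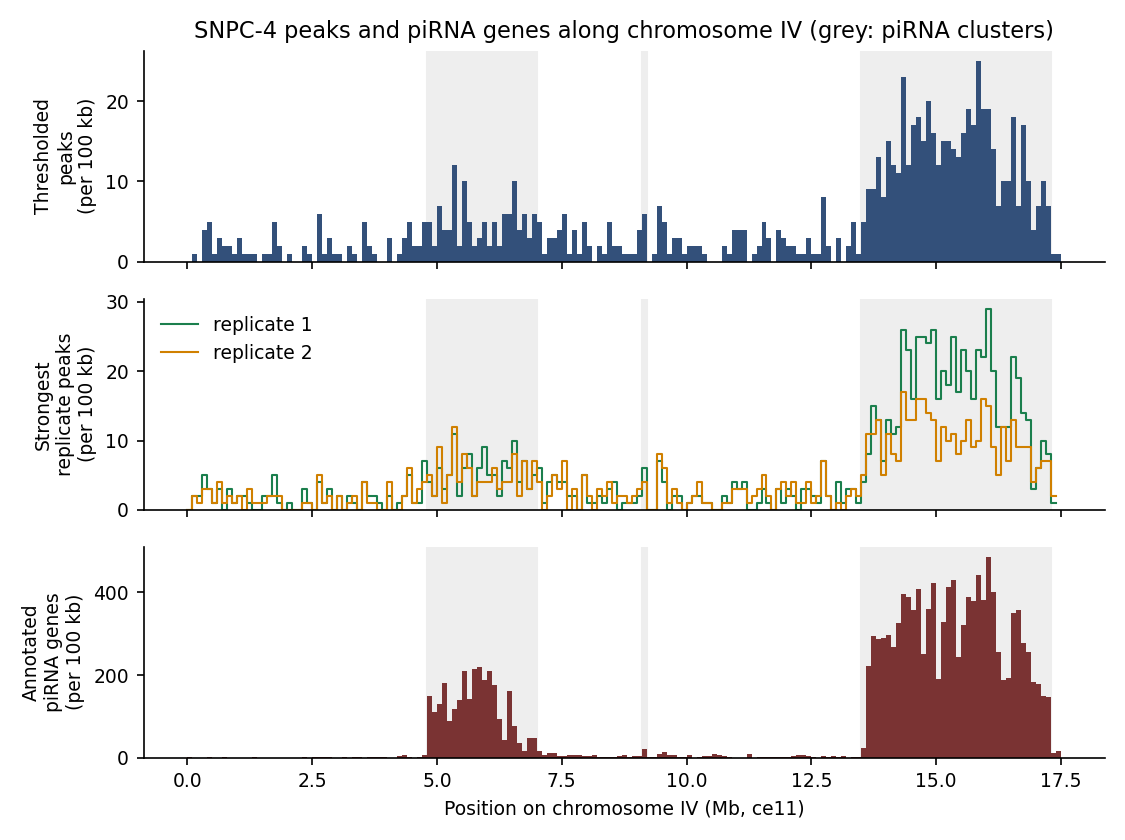
Peaks and annotated piRNA genes per 100 kb window along chromosome IV (position in Mb, ce11), with the piRNA clusters in grey. The upper panel shows the thresholded peaks, the middle panel the 2345 strongest peaks of each replicate and the lower panel the piRNA genes; the cluster at the right end held 508 thresholded peaks.

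Peaks were also counted at single piRNA genes. Those near a piRNA 5′ end numbered 337 against 150 expected from placement within the chromosome (ratio 2.24, adjusted permutation p = 0.000225), and nearly all of them, 324, lay inside the clusters. Placement inside the clusters gave 292 there, a ratio of 1.11 (permutation p = 0.015). Inside the clusters 51.8% of peaks were near a piRNA 5′ end and 10.4% were near a spliced leader, snRNA, tRNA or snoRNA gene. Of 15362 piRNA loci, 840 had a peak (5.47%, 5.12 to 5.84), above the share of protein-coding genes (adjusted exact p = 1.41e-43). These 840 loci stood by the same 337 peaks, so they are not independent, and the interval and exact p are too narrow. The comparison takes protein-coding genes of all chromosomes, and those of chromosome IV had a peak at 4.30% against 2.22% elsewhere. The replicates differed in the share of piRNA loci, with 8.10% in replicate 1 and 3.93% in replicate 2. The strongest peak at piRNA genes, with signal 602 (replicates 354 and 269), had its summit outside protein-coding genes, 144 bp downstream of the 5′ end of *21ur-3160* (IV, 14224968 to 14224988) and 149 bp upstream of that of *21ur-5470* (IV, 14224943 to 14224963). The next, with signal 521, lay in an intron of *pkd-2* 134 bp downstream of the 5′ end of *21ur-73* (IV, 15234326 to 15234346), which is uncertain for its repeated flanks. In the stronger part of the list, 1172 peaks, the excess was 1.21 and was no longer called (adjusted permutation p = 0.0902), and the share of piRNA loci, 1.15%, was below that of protein-coding genes without passing the test (adjusted exact p = 0.278). Measured against entries of the pooled list below the threshold, which by label include background, the ratio was 0.993 (adjusted exact p = 0.927).

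Many piRNA genes carry the motif CTGTTTCA upstream, and genes with and without it had peaks at similar shares. On chromosome IV 629 of 11397 piRNA genes with the motif had a peak (5.52%) and 198 of 3317 without it did (5.97%), an odds ratio of 0.920 (p = 0.325, two-sided Fisher's exact test). At summits the exact motif was sought, without the 1 mismatch allowed upstream of genes. Inside the clusters it occurred in 18.1% of 625 summits against 6.36% by placement on the chromosome (ratio 2.84, permutation p = 0.0002, the smallest that the placements can give). Outside the clusters it occurred in 0.523% of 1720 summits against 1.84% (ratio 0.284, permutation p = 0.0002). Compared with random places in the same part of the chromosome, a test chosen after the result was seen, the ratio was 1.16 inside the clusters (permutation p = 0.0972) and 0.443 outside them (permutation p = 0.0082). In the stronger part of the list the ratio inside the clusters was 0.923 by placement on the chromosome (permutation p = 0.872). In that stronger part, 114 of 11397 piRNA genes with the motif had a peak and 58 of 3317 without it (odds ratio 0.568, exact p = 0.000874). That part held only 82 peaks near any piRNA gene, and 1 summit can stand by several genes, with and without the motif. The genes are therefore not independent, and the exact tests on piRNA genes overstate the evidence.

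The 87 peaks near snRNA and spliced leader genes shared short sequences at their summits. Of 31202 words of 8 bases, 229 occurred within 50 bp of these summits more often than at the other 2258 (Fisher's exact tests, adjusted). The word TACCGACA occurred at 12 of the 87 and at 2 of the others (adjusted exact p = 8.45e-12). The commonest of the 229, CGGAACCC, occurred at 24.1% of the 87 and at 4.74% of the others (adjusted exact p = 5.72e-06). It was found at 16.7% of the peaks near snoRNA genes and at 0 of 268 near tRNA genes, which allows a share of up to 1.12%. Genes of the same family share sequence, so words from repeated copies are not independent.

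The signal of the peaks differed between the gene groups. Peaks near snRNA or spliced leader genes had a median signal of 239.9, those near tRNA genes 70.8, those near protein-coding genes 60.9 and those near piRNA genes 50.6. All 6 pairs differed, 5 of them with an adjusted p of 1.2e-05 from an unadjusted p of 1e-05, the smallest that 100000 resamples can give, and tRNA against protein-coding with 0.00024 (permutation tests, two-sided). Peaks near snoRNA genes, added after the data were seen, had a median of 134. Peaks are not replicates. By rank in replicate 1, the pairs among tRNA, piRNA and protein-coding genes were not called, with adjusted permutation p of 0.149, 0.856 and 0.0797 for tRNA against piRNA, tRNA against protein-coding and piRNA against protein-coding.

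Summits took different places at the different groups. They lay upstream of the 5′ end by a median of 43 bp at spliced leader genes, 31 bp at snRNA genes and 44 bp at snoRNA genes. At protein-coding genes the median summit lay 105 bp upstream, with quartiles at offsets of -154 and -43 bp, negative being upstream. Only summits within 200 bp entered this median. Protein-coding genes had 463 peaks within that limit (187 expected) and 879 within 500 bp (445 expected). Their median therefore depends on the limit and is not read as a preferred place. Of the 67 summits near snRNA genes 64.2% were upstream, and the U2 family had its median 26 bp downstream of the 5′ end. At tRNA genes the median summit lay 21 bp inside the gene, and 35.1% of the 262 summits were upstream. At piRNA genes the median lay 1 bp downstream of the 5′ end, but the quartiles lay 50 bp upstream and 80 bp downstream. The summits there were spread to both sides, and the median marks no preferred place.

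**Figure D3:**
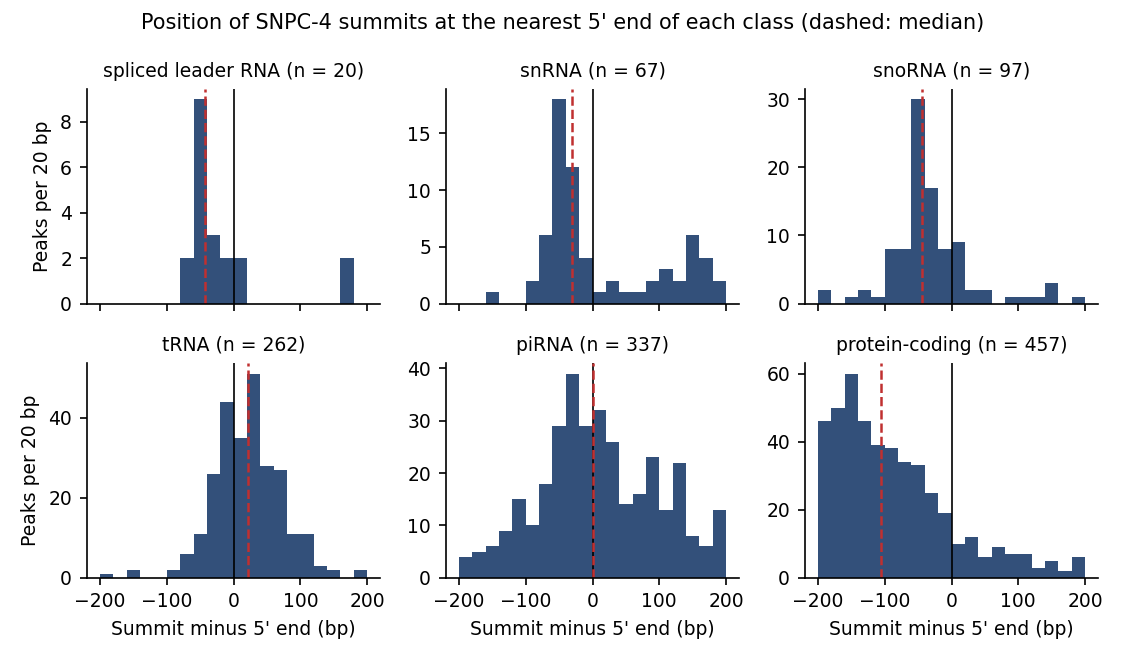
Number of nuclear peaks per 20 bp by the position of the summit relative to the nearest 5′ end of each class, in bp, negative values being upstream. Dashed lines mark the medians; the tRNA median lay 21 bp downstream and the snoRNA median 44 bp upstream.

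Among 10 lists of protein-coding genes, whose defining symbols were fixed before the data were examined, ribosomal protein and histone genes had peaks more often than other protein-coding genes, and chemoreceptor genes less often. Of 78 ribosomal protein genes 7 had a peak (8.97% against 2.56%, odds ratio 3.75, adjusted exact p = 0.0202 over the 10 lists). The 3 with the highest signal were *rpl-12* (IV, 13239587 to 13240651) at 105, *rps-12* (III, 5679298 to 5680187) at 93.8 and *rps-27A* (III, 3068310 to 3069210) at 74.0. At *rpl-12* the replicates gave 60.9 and 7.22. Most ribosomal protein genes had a peak slightly farther upstream: within 500 bp it was 55 of 78 (70.5%, 59.6 to 79.5) against 5.26% of other protein-coding genes, an odds ratio of 43.1 (adjusted exact p = 1.63e-50). The nearest summit was upstream in 54 of the 55, at a median of 289 bp, and the share was 61.5% ± 1.81 (SD, n = 2) over the replicates. Without peaks near noncoding RNA genes, chosen after the data were seen, it was 55.1% (adjusted exact p = 3.76e-36). The strongest of these peaks, named after their values were seen, stood at *rpl-18A* (IV, 4749123 to 4749778) with signal 408, *rpl-3* (III, 3867854 to 3869587) with 373 and *rpl-15* (IV, 653480 to 654576) with 349.7. Of 72 histone genes 6 had a peak (8.33%, odds ratio 3.45, adjusted exact p = 0.0360), led by *his-67* (I, 9988452 to 9988763) at 161, *his-37* (V, 9547105 to 9547607) at 94.2 and *his-61* (IV, 7485834 to 7486217) at 89.9. The flanks of *his-61* held repeated sequence, so its assignment is uncertain. The histone call was lost within 100 bp (1.39%, adjusted exact p = 0.869), within 500 bp (9.72%, adjusted p = 0.196), inside the peak (0%, adjusted p = 1.0) and in replicate 2 alone (5.56%, adjusted p = 0.168). Of 1197 chemoreceptor genes, expressed mainly in sensory neurons, 3 had a peak (0.251% against 2.74%, odds ratio 0.0893, adjusted exact p = 1.08e-09): *sru-9* at 96.4, *srh-16* at 59.1 and *srt-48* at 43.3.

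The other 7 lists did not pass their tests. Germ granule and small RNA factors had peaks at 3 of 27 genes (11.1%, adjusted exact p = 0.0738), and heat shock proteins at 2 of 24 (8.33%, adjusted exact p = 0.212). The list of piRNA factors had 1 of 15 (6.67%, adjusted exact p = 0.465), which was *snpc-4*, and neuropeptides had 3 of 147 (2.04%, adjusted exact p = 1.0). Collagens had a peak at 0 of 156 genes, which allows a share of up to 1.92% (adjusted exact p = 0.0738). Major sperm proteins had 0 of 31, which allows up to 9.68%, and vitellogenins 0 of 6, which allows up to 50% (adjusted exact p = 1.0 for both). The ribosomal protein call, kept within 500 bp, was lost within 100 bp of the 5′ end (2.56% of members, adjusted exact p = 0.470) and where the 5′ end had to lie inside the peak (5.13%, adjusted p = 0.183).

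The loci tied to the strain were looked at for peaks that stood apart. The *snpc-4* gene itself (WBGene00001568, I, 8962322 to 8966129) had a peak 190 bp upstream of its 5′ end with signal 124, with 50.4 in replicate 1 and 59.8 in replicate 2. Within 20 kb of the gene lay 5 thresholded peaks, more than around 97.0% of protein-coding genes, whose median was 1. The replicates had 4 and 5, and the pooled ChIP list given to IDR held 35 entries there against a median of 10. The strongest of the 5, with signal 209, lay 100 bp from the 5′ end of *spd-2*. No peak lay within 20 kb of *unc-119* (III, 10902641 to 10908935), the gene mutated in the strain. Of the genes for piRNA production, *prg-1*, *prde-1*, *tofu-4* and *tofu-5* had no peak within 200 bp of the 5′ end.

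Both replicates carried most thresholded peaks, and their strongest peaks overlapped in part. A summit among the 2345 strongest of replicate 1 lay within 200 bp of 72.4% of the thresholded peaks (70.6 to 74.2), and of replicate 2 within 200 bp of 69.3% (67.4 to 71.1). The strongest peaks of replicate 1 were shared with those of replicate 2 for 1234 of 2345 (52.6%, 50.6 to 54.6), where chance placement gave 1.83%. Across 2217 peaks with a value in both replicates, the log10 signals had a Pearson correlation of 0.626 and a Spearman correlation of 0.433. These are correlations across peaks, which are not independent replicates.

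The mitochondrial genome carried 27 peaks that covered 93.8% of its 13794 bp, with a median signal of 380.0 against 60.4 for nuclear peaks. The peak with the highest signal of all, 3238, had its summit in *CYTB*, and another with signal 1874 had its summit in *ND5*. Of mitochondrial RNA genes, a tRNA gene at 13275 to 13327 stood by a signal of 1030.2, with 764 and 300.2 in the replicates. The ribosomal RNA gene at 10403 to 11354 stood by a signal of 509, with 373 in replicate 1 and 20.8 in replicate 2, and the one at 898 to 1593 by 494, with 224 and 331. The strongest peaks of replicate 1 included 27 mitochondrial ones and those of replicate 2 included 25. Peaks over nearly all of this genome do not single out the genes named here. Whether they come from binding or from background was not tested, as control DNA was not analysed.

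The authors also gave lists on the older build ce10, where the thresholded list held 1827 peaks, 732 of them on chromosome IV (40.1%). It held 0 mitochondrial peaks, although the pooled list given to IDR on ce10 held 29 mitochondrial entries. None of its 1827 lines occurred in the pooled or the replicate lists on ce10, and 1615 of its peaks (88.4%, 86.8 to 89.8) had a pooled summit within 200 bp. On ce11, by contrast, all 2345 thresholded peaks were the 2345 strongest of the pooled list, line for line.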

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

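The alternatives without mitochondrial peaks, without peaks near noncoding RNA genes, with placement inside the same part of the chromosome, with chromosome IV left out, and the count of peaks on ce10 were chosen after the data were seen; all others were set before the data were examined. Of those set before, 216 left the result with its direction and its side of the threshold, or within its spread, as did 43 of those chosen later. Another 12 weakened a call, 7 brought one, 12 moved a value and 4 reversed a direction, and of those chosen later 4 weakened a call and 3 reversed a direction. The ratios for spliced leader, snRNA, tRNA, snoRNA, other noncoding RNA and protein-coding genes, for chromosome IV and for the piRNA clusters kept direction and call under every alternative run on them.

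Sharing between the replicates was 55.3% with 1 bp of overlap, 43.2% with 50% reciprocal overlap, 45.3% within 100 bp and 57.8% in the stronger part of the list. In that stronger part the piRNA ratio was 1.21, the piRNA share 1.15%, the motif odds ratio 0.568, the summit motif ratio inside the clusters 0.923, and 3 peaks lay around *snpc-4*; it holds fewer peaks by construction. With entries of the pooled list below the threshold as background the piRNA ratio was 0.993, and with placement inside the same part the summit motif ratio was 1.16. The microRNA share was 9.58% within 500 bp and 3.83% with the 5′ end inside the peak, both called, and 3.45% to 4.60% with either replicate left out, called with replicate 1 left out. The ribosomal RNA share was 4.55% within 100 bp, 13.6% within 500 bp and 5.0% without mitochondrial peaks, none called, and 9.09% to 13.6% with either replicate left out, not called with replicate 2 left out. Of the fixed lists 1 passed within 100 bp and 1 with the 5′ end inside the peak, where histones had 0%. Within 500 bp the ribosomal protein share was 70.5%, or 55.1% without peaks near noncoding RNA genes, both called. With chromosome IV left out, the ratios of chromosomes I, II and III were 1.05, 1.13 and 1.25; the fixed total accounts for their lower values with IV. Germ granule factors passed in replicate 2 alone at 14.8%, and heat shock proteins in replicate 1 alone at 16.7% and within 500 bp at 20.8%, lost there without peaks near noncoding RNA genes (12.5%, adjusted exact p = 0.158). By rank in replicate 1, on which lower ranks are stronger, the differences of median ranks were 220.0 for piRNA minus tRNA, 34.5 for protein-coding minus tRNA and -185.5 for protein-coding minus piRNA, and none was called. Beyond the smaller list the cause was not tested. Read depth was not used here, so its effect was not measured.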

Other observations

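The tests on summit position, on spliced leader and on snRNA genes alone and on genes by chromosome were chosen after the result was seen. So were those on tRNA genes inside the clusters and on the word upstream of genes of each class. The reading of bounds by intervals and not by point values was also chosen then. The other tests were set before the result was seen.

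Within the snRNA class, assigned to families by conserved elements, peaks were present at 10 of 12 U1 genes, 13 of 19 U2 genes, 4 of 5 U4 genes, 10 of 11 U5 genes, 8 of 22 U6 genes and 4 of 20 genes assigned to no family. The last 4 include *mir-1831* and *T27E4.22*, which count the peaks of the U1 genes *sup-39* and *T27E4.12* again. SmY genes, nematode snRNA genes whose products act in trans-splicing, had peaks at 7 of 10: all 7 on chromosome IV, among them *smy-1*, *smy-7* and *smy-12*, and 0 of the 3 on chromosome V (*smy-4*, *smy-5* and *smy-6*). These genes were named after their values were seen, and the difference between families was not tested. Of the snoRNA genes, 61 of 163 outside a protein-coding gene of the same strand had a peak (37.4%) and 34 of 183 inside one did (18.6%), an odds ratio of 2.62 (p = 0.000106, two-sided Fisher's exact test). The word CGGAACCC stood within 100 bp upstream of 17 of 95 snoRNA genes with a peak (17.9%) and 3 of 251 without (1.2%), an odds ratio of 18.0 (exact p = 4.96e-08), at a median of 63 bp upstream. It also stood upstream of 5 of 511 protein-coding genes with a peak and 5 of 19455 without (odds ratio 38.4, exact p = 2.44e-06). In the classes the word came from the difference did not pass: 19 of 56 snRNA genes with a peak had it against 7 of 43 without (odds ratio 2.64, exact p = 0.0653), as did 5 of 18 spliced leader genes against 0 of 13 (exact p = 0.058). None of 284 tRNA genes with a peak had it. The 5 protein-coding genes, named after their values were seen, were *hsp-16.20*, *wapl-1*, *syp-3*, *W06D4.3* and *T22A3.12*, and the peaks at *hsp-16.20* and *W06D4.3* were also near an snRNA and a spliced leader gene.

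Nuclear tRNA genes of chromosome IV had a peak at 51 of 71 (71.8%), against 233 of 541 on the other chromosomes (43.1%), an odds ratio of 3.37 (p = 6.44e-06, two-sided Fisher's exact test). The shares were 69.0% against 37.7% in replicate 1 and 73.2% against 49.2% in replicate 2. The rise was not confined to tRNA genes: on chromosome IV snoRNA genes had a peak at 42.4% against 24.4% (odds ratio 2.28, exact p = 0.00645) and protein-coding genes at 4.30% against 2.22% (odds ratio 1.98, exact p = 1.36e-10). Chromosome IV held 48.9 peaks per Mb against 17.7 on the other nuclear chromosomes, so random placement alone puts more summits near its 5′ ends. The exact tests do not allow for this density, which matters most for the low protein-coding shares. No rise was seen for snRNA genes as a whole, at 55.6% against 57.1% (odds ratio 0.938, exact p = 1.0). That class mixes families with unlike shares, such as SmY and U6, and the families were not tested by chromosome. A rise within a family is therefore not excluded, and the SmY genes with a peak all lay on chromosome IV. Of the tRNA genes inside the piRNA clusters 35 of 41 had a peak (85.4%), against 16 of 30 elsewhere on chromosome IV (53.3%), an odds ratio of 5.10 (exact p = 0.00664). The tRNA genes of chromosome IV outside the clusters did not differ from those of other chromosomes past the threshold (odds ratio 1.51, exact p = 0.345). By product, 0 of 22 groups of tRNA genes, 1 of them with no amino acid given, differed from the other tRNA genes after adjustment of Fisher's exact tests. Before adjustment 1 group had an exact p under 0.05, aspartate with 18 of 27 genes (p = 0.0466). Summits near spliced leader, snRNA and snoRNA genes had a median offset of -39 bp and those near tRNA genes of 21 bp, a difference of -60.0 bp (p = 1e-05 by permutation, the smallest that 100000 resamples can give).

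Peaks crowded into the piRNA clusters. Base composition did not account for it: random places matched to the GC content of the summits put 300.5 peaks in the clusters against 625 seen, a ratio of 2.08 (permutation p = 0.0002, the smallest that the placements can give). Summits at piRNA 5′ ends inside the clusters were 1.11 times as frequent as by placement there (324 against 292, permutation p = 0.015). This ratio is below the bound of 1.2 set in advance, but no interval was computed for it. Placement alone put 292 of the 625 within 200 bp of a piRNA 5′ end, which leaves the measure limited room. A part played by piRNA 5′ ends is therefore not settled. A background that raises peaks of any strength in the clusters cannot be told apart from binding here. Of the 9086 pooled entries below the threshold that were compared, 66.02% lay there, against 73.0% of the thresholded peaks. The difference of 6.99 percentage points lies above the bound of 5 points, but its interval (3.86 to 10.1) reaches to both sides of that bound. The rule set in advance asked for a difference above 5 points with an interval that excludes 0, and by it this background was set aside. The stricter reading by the whole interval, chosen after the result was seen, leaves it open. No biological explanation was tested, since the design has a single group.

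Spliced leader and snRNA genes without a peak may lack uniquely placed reads. For spliced leader genes the values go that way, since 0 of 11 genes with no unique word in their flanks had a peak and 13 of 14 with at least 80% unique words did, 34.8 percentage points (17.3 to 53.0) above the share of all. All 12 *sls-1* genes, which lie in tandem copies on chromosome V, had no peak, which allows a share of up to 25%, and 18 of 19 *sls-2* genes had one. The 11 genes with no unique word are all *sls-1* genes, so uniqueness and family cannot be told apart here. Within *sls-2*, the gene without a peak, *sls-2.6*, had 98.1% unique words. By contrast, *sls-2.12* (46.2%) and *sls-2.19* (57.3%) had peaks. For snRNA genes as a whole the values did not go with a lack of uniquely placed reads. The share at 80% unique words or more minus that of all was -9.34 percentage points (-22.4 to 3.72). Median uniqueness was 75.9% without and 72.8% with a peak. The class mixes families: the 20 genes of no family had a median of 99.1%, and 4 had a peak. Among these 4, *mir-1831* and *T27E4.22* share their peak with a U1 gene. Repeats stay open for snRNA genes with few unique words. Of those with no unique word 0 of 2 had a peak, and *T27E4.10* (8.11% unique words) and *T27E4.11* (10.8%) had none. The same was true of U6 genes such as *K09B11.11* (29.7%) and *F54C8.9* (40.5%). In the U2 family, however, 13 of 19 genes had a peak at a median uniqueness of 40.3%. Over both classes together the difference of 3.08 points (-7.96 to 14.1) reached to both sides of the bound of 5 points, and no biological explanation was tested.

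Peaks gathered around *snpc-4*. Neighbouring noncoding RNA genes do not account for them, since 1 of the 5 thresholded peaks within 20 kb lay near such a gene. Extra copies of the locus in the transgene remain a candidate explanation. The pooled ChIP list given to IDR, which by label includes background, held 35 entries within 20 kb, against a median of 10. That number was reached by 4.24% of protein-coding genes. Control DNA was not analysed. The extent of the transgene is not given in the sources used here, and no biological explanation was tested.

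Of the thresholded ce10 peaks 940 (51.5%, 49.2 to 53.7) had 1 of the 1827 strongest nuclear pooled ce10 summits within 200 bp, against 73.5% and 70.7% of the equally many strongest peaks of replicates 1 and 2.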
